A study of Homo sapiens with 3 samples.

How the data were processed

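Total RNA was extracted with TRIzol from LNCaP cells and hybridised on two-colour arrays, and a service company ran the arrays and acquired the data, per the labels. The probe identifiers are of Agilent type. The deposited intensity tables hold 2 signal columns per array and 34183 probes, of which 56 are control or spike-in probes. The columns are called raw in the file headers, but the values look background-corrected and, at the median, dye-balanced: both medians of an array were close (94.2 and 95.1 for 5'-Lys KD, 70.9 and 70.9 for 5'-Asp KD, 79.9 and 80.9 for 3'-Asp KD), and all values were positive. Near the floor the columns were not balanced. The negative control probe had 4.59 and 2.81, 4.10 and 2.36, and 3.88 and 2.20 on these arrays, so ratios of dim genes can lean towards the first column. Extraction software and settings are not given in the sources used here, and no detection or saturation flags were used. The deposited series values were signed fold changes of the first over the second column multiplied by 1 constant per array (log2 of -0.021, -0.017 and -0.013), with no other deviation above 1.74e-06, so scale, centring and direction of that table are known relative to the columns. Their medians were 1.06, 1.07 and 1.05.

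Arrays were mapped to groups by the treatment labels, with n = 1 per group. Labels and column names disagree on which column holds the knockdown for both Asp arrays. The labels' dyes set the direction in the main results, as fixed before the data were examined, and the opposite sign was added as an alternative after the data were seen. In a two-colour array a gene-specific dye effect adds to the ratio, and with 1 dye orientation it cannot be removed from a single array.

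Gene symbols came from the platform annotation of 2015, in which 28048 probes had 1 symbol, 0 had several and 6079 had none. Of these symbols 25515 were set through the unversioned transcript accession to current NCBI RefSeq names, 2179 were kept as current and 354 kept though not current. Log2 signals of a gene's probes were averaged, which gave 20399 genes, and the 10200 with a mean signal at or above the 50th percentile (log2 of 7.03) were taken as measured. Of these 3086 had more than 1 probe, with a median SD between probes of 0.17, 0.15 and 0.16 for the log2 ratios of 5'-Lys KD, 5'-Asp KD and 3'-Asp KD. The lowest log2 signal of a measured gene in any column was 4.66. The number of arrays limits the precision.

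Because the intensities already looked processed, they were used as given, and each array's log2 ratio was centred on its median over measured genes. Alternatives were limma (3.58.1, R 4.3.3) within-array loess, normexp background correction with an offset of 50, the deposited signed folds, the mean Cy5 signal of all arrays after Aquantile scaling as the control, no filter, the 75th percentile as filter, the brightest probe per gene and a 1.5-fold threshold. Added after the data were seen were the column-name direction, centring on all named genes, and leaving out small RNAs and C1QTNF5. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 did the remaining steps.

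Each comparison counted measured genes at least 2-fold apart, with no p-value. Before the data were examined, 30 gene lists were fixed. For each list with at least 5 measured members (26 lists, 78 combinations with an array), the median log2 ratio was placed among 10000 random lists of the same size matched over 20 bins of mean signal. A list stood apart below the 0.5th or above the 99.5th percentile, which lists of randomly drawn genes do about 1 time in 100, and 19 combinations did so. Members of a list that move together can leave the bounds more often than this with no knockdown effect, so 19 is not to be set against that rate. Some lists share members, such as SLC7A11 (ATF4 and NRF2), BIRC3 (NF-kB and apoptosis) and ACSL3 (androgen response and fatty acid synthesis). For differences between arrays the same was done with the difference of log2 ratios. The interval of a list median comes from 2000 bootstrap draws of its members, so it holds no spread between arrays or cultures. The shared-control correlation and overlap come from 20 simulations, in which the Cy5 SD of each gene was the SD of both knockdown and control.

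Named genes were fixed by rule: per knockdown the 12 highest and 12 lowest ratios among genes at least 1.5-fold away in the same direction against both the array's own and the mean Cy5 signal, 10 per direction shared by all arrays or differing between a pair, 3 per direction in each list, and a few genes chosen in advance such as ANG and KLK3. Names of the type of uncharacterised loci were left out. MYL9, INHBB and the genes whose signal stood outside all other columns were chosen after their values were seen. Some genes named in advance were not analysed here.

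The steps were tested on simulated arrays of 10200 genes with the real mean signals and Cy5 spreads. In the simulated 5'-Lys array 99% of 100 genes changed 3-fold and 3% of 100 changed 1.5-fold were called at 2-fold in the right direction, and 0.70% of unchanged genes were called. Corresponding values were 98%, 5% and 0.77% for the simulated 5'-Asp array and 99%, 6% and 0.68% for the simulated 3'-Asp array. A planted list was found on all 3 arrays, and 6 of 600 unchanged list and array combinations (1.0%) stood apart. The unchanged lists held random genes with independent errors, so this rate does not cover lists whose members move together.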

Results

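Messenger RNA levels were measured in LNCaP cells, an established androgen-responsive line of human prostate cancer, after small interfering RNAs (siRNAs) had been directed against 3 SHOT-RNAs. SHOT-RNAs are sex hormone-dependent fragments cut from mature transfer RNAs by the ribonuclease angiogenin, and the labels name each target by the end of the tRNA it derives from and by its amino acid. The knockdowns were of the 5' fragment of a lysine tRNA (5'-Lys KD), the 5' fragment of an aspartate tRNA (5'-Asp KD) and the 3' fragment of an aspartate tRNA (3'-Asp KD). Cells received 20 nM siRNA for 5'-Lys KD and 5'-Asp KD and 10 nM for 3'-Asp KD, and were harvested after 72 h. Each knockdown was hybridised on 1 two-colour array against cells given an siRNA to Renilla luciferase, so there were 3 arrays, 1 per knockdown, and no replicate. No test was therefore possible, and "higher" and "lower" below describe these arrays.

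The question put by the design is how mRNA levels after each knockdown differ from those after the control siRNA. Values are log2 ratios of the deposited intensities for 10200 measured genes, centred on each array's median, and single probes stand behind most genes. The SD of the ratios across genes was 0.39 for 5'-Lys KD, 0.33 for 5'-Asp KD and 0.30 for 3'-Asp KD. The closest measure of error was the SD of a gene's Cy5 (control) signal over the 3 arrays, with a median of 0.11 and a 95th percentile of 0.33 on the log2 scale. If 1 control RNA served all arrays, this SD and the simulations built on it hold technical spread and no spread between cultures. Differences between arrays that both columns share cancel in the ratio, so this SD can also overstate its error. The simulation of unchanged genes drew both columns independently, so the share of genes it calls may be too high or too low. The targeted tRNA fragments were not analysed here, so the arrays give no check of the knockdowns themselves.

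The direction is settled for the 5'-Lys array and not for the other 2 arrays. The sample labels put the knockdown in Cy3 and the control in Cy5 throughout, whereas the deposited column names give the first signal column to the knockdown on the 5'-Lys array and to the control on both Asp arrays. The 10 spike-in probes had nearly the same first over second ratios on all arrays (Pearson r of 0.999 or more for each pair), so the first column was the same dye on each. All signed values below go Cy3 over Cy5, which by the dye labels is the knockdown over the control. If the column names were right, each sign for 5'-Asp KD and 3'-Asp KD would turn.

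After 5'-Lys KD, cell cycle and androgen-induced genes were lower, while p53 targets and a few interferon-induced genes were higher. The highest ratios apart from that of C1QTNF5, treated with the genes shared by all arrays, were those of ACTA2, smooth muscle actin, at 9.61-fold and OASL, an interferon-induced gene, at 9.41-fold. CEND1, a neuronal regulator of cell cycle exit, was 5.64-fold higher and the interferon-induced IFIT1 was 5.61-fold higher. The lowest ratio was that of SEMA3C, a secreted semaphorin, at 5.53-fold lower, although its Cy5 signal had an SD of 0.56 between arrays. At the 2-fold threshold 62 genes were higher and 138 lower, and centring on all named genes instead moved this split to 45 and 183. The counts are 0.61% and 1.35% of measured genes, and together 200 of 10200. With the Cy5 spread as the error of both channels 0.70% of unchanged genes passed in simulation. That rate counts both directions together, so it belongs beside the 200.

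Among further genes higher with 5'-Lys KD, BIRC3, an NF-kB-induced inhibitor of apoptosis, was 4.12-fold higher, SYTL2, a vesicle trafficking protein, 3.78-fold, TNFRSF12A, the receptor of the cytokine TWEAK, 3.73-fold, and CLU, the extracellular chaperone clusterin, 3.28-fold. Of the nuclear and nucleolar RNAs, SCARNA13 was 4.97-fold, RNU2-1 4.12-fold and SNORA28 3.29-fold higher. On the lower side stood GTF2E2, a subunit of the general transcription factor TFIIE, at 3.44-fold, PIMREG, a mitotic regulator, at 3.18-fold, the transcription factor RFX6 at 3.16-fold and the potassium channel gene KCND2 at 3.16-fold. INSIG1, the sterol-regulated retention factor of the endoplasmic reticulum, was 3.14-fold lower, mitochondrial glycerophosphate dehydrogenase GPD2 3.05-fold, TMTC2 3.01-fold, SPRING1, a regulator of SREBP processing, 2.99-fold and RFXAP, a regulator of MHC class II genes, 2.92-fold. E2F7, a repressor of cell cycle genes, had a mean 3.22-fold lower, but its 2 probes disagreed with an SD of 1.58 on the log2 scale.

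The 24 measured G1/S replication genes had a median log2 ratio of -0.59 with 5'-Lys KD, below all 10000 random lists of matched signal. In this list 13 genes were at least 1.5-fold lower and 0 higher, led by E2F1 (-1.27), MCM6 (-1.13) and POLA1 (-0.89). The 30 G2/M genes also had a median of -0.59, below all random lists, with 16 members at least 1.5-fold lower, among them TOP2A (-1.46), CENPF (-1.12) and TTK (-1.01). The proliferation marker MKI67 stood at -0.83. Of 26 androgen-induced genes 8 were at least 1.5-fold lower and 0 higher, and their median of -0.51 again lay below all random lists. KCNN2 (-1.08), FKBP5 (-1.05) and ACSL3 (-0.95) were the lowest, KLK3, which encodes prostate-specific antigen, had -0.70 and TMPRSS2 -0.52.

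The 21 p53 targets had a median of 0.49 with 5'-Lys KD, above all random lists, and of 0.23 against the mean Cy5 signal of all arrays, at percentile 99.4 and inside the bounds. At least 1.5-fold higher were 5 of them, including the cyclin-dependent kinase inhibitor CDKN1A (1.40), GDF15 (0.86) and PHLDA3 (0.81), and 1, SESN1 (-0.79), was at least 1.5-fold lower. The 17 apoptosis regulators had a median of 0.32 at percentile 99.9 (bootstrap interval -0.06 to 0.56, which holds 0), with BIRC3 (2.04), BIK (1.42), BAK1 (1.13) and PMAIP1 (0.61) at least 1.5-fold higher. BIRC3 inhibits apoptosis and the other 3 promote it. This list stood apart under 6 of 9 other settings, and not against the mean Cy5 signal (0.23, percentile 98.6), without the signal filter (0.22, 99.3) or with that filter at the 75th percentile (0.35, 99.1). Of 14 replication-dependent histone genes 5 were at least 1.5-fold higher, led by H2AC8 (1.09) and H2AC6 (0.88, and 0.69 for a probe still under the former symbol HIST1H2AC), and the median of 0.50 lay above all random lists but was -0.08 against the mean Cy5 signal of all arrays. Probes of such histone genes may bind more than 1 family member.

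The interferon list as a whole did not stand apart, with a median of 0.06 at percentile 71.2, since 5 of its 17 members were at least 1.5-fold higher and 11 lay within 1.5-fold. OASL (3.23), IFIT1 (2.49), IFI6 (1.15), ISG15 (1.04) and ISG20 (0.71) made up these 5, and DTX3L (-0.66) was lower. MX1 had -0.39. On the 5'-Asp array OASL had 0.74, and on the 3'-Asp array no member was 1.5-fold away from 0. Among 6 NF-kB genes BIRC3 and RELB (1.25) were higher, and the median of 0.24 lay at percentile 94.5. The 70 ribosomal proteins had a median of -0.09 at percentile 0.32, with no member 1.5-fold away from 0, and stood apart under 7 of 9 other settings.

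**Figure D1:**
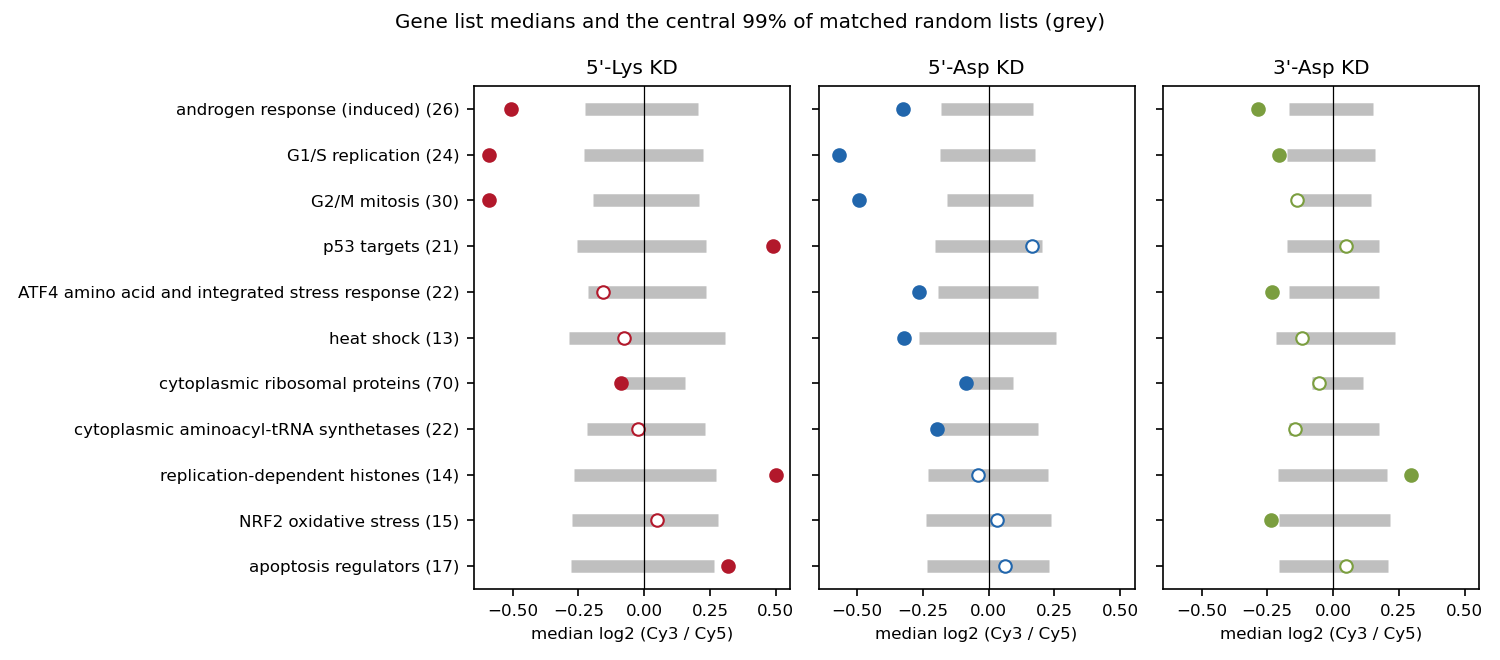
Median log2 ratio (Cy3 over Cy5) of the 11 gene lists that stood apart on at least 1 array, with the number of measured genes in brackets and 1 panel per array. Grey bars span the central 99% of matched random lists, and filled points lie outside them. The G1/S median was -0.59 for 5'-Lys KD, -0.57 for 5'-Asp KD and -0.20 for 3'-Asp KD, and signs of both Asp panels would turn by the column names.

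With 5'-Asp KD, read by the dye labels, cell cycle and androgen-induced genes were again lower, and GDF15, a stress-induced cytokine and p53 target, was 3.41-fold higher. INSIG1 had the lowest ratio at 3.30-fold lower, followed by the redox protein gene TXNDC15 at 2.85-fold, the ribonucleotide reductase subunit gene RRM2 at 2.81-fold and SDHD, a subunit of succinate dehydrogenase, at 2.75-fold. For SDHD 3 probes gave this ratio with an SD of only 0.08. At least 2-fold higher were 37 genes and lower 54, and centring on all named genes moved this to 25 and 78. These are 0.36% and 0.53% of measured genes, and together 91 of 10200. In the simulation 0.77% of unchanged genes passed with both directions counted together, so that rate belongs beside the 91 and not beside either share. Given the limits of its error measure, the simulation does not show that these counts exceed those with no change. By the column names 54 would be higher and 37 lower.

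Other genes with a high Cy3 signal on the 5'-Asp array were TNFRSF12A (3.42-fold), RNU2-1 (3.57-fold), SCARNA13 (3.12-fold), SNORA28 (2.85-fold), C1QTNF6 (2.77-fold), NBEA (2.62-fold), the pro-apoptotic BIK (2.62-fold), the metalloproteinase MMP24 (2.61-fold), LRRN1 (2.57-fold) and the neuronal tubulin TUBB3 (2.56-fold). On the low side were the magnesium transporter NIPA1 (2.66-fold), the mitochondrial carrier homologue MTCH2 (2.62-fold), ZNF652 (2.57-fold), the fatty acid hydroxylase CYP4V2 (2.54-fold), the complex III assembly factor LYRM7 (2.53-fold), the Sm-like protein LSM6 (2.48-fold) and the phosphatidate phosphatase LPIN2 (2.47-fold). NBEA, LRRN1 and TUBB3 had Cy5 signals with an SD of 0.60, 0.50 and 0.49 between arrays.

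For 5'-Asp KD the G1/S list had a median of -0.57 and the G2/M list -0.49, both below all random lists, with 12 of 24 and 14 of 30 members at least 1.5-fold lower and 0 higher. RRM2 (-1.49), PCNA (-1.07) and NUF2 (-1.01) were the lowest of these. Androgen-induced genes had a median of -0.32, below all random lists, and 8 of 26 were at least 1.5-fold lower, including ZBTB10 (-0.95), NDRG1 (-0.83), ELL2 (-0.76), KLK2 (-0.73) and KLK3 (-0.71). TMPRSS2 (0.58) and HOMER2 (0.58) went the other way. Probes of KLK2 and KLK3, which are close relatives, may bind both transcripts.

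Further lists lay low on the 5'-Asp array. The 22 ATF4 and amino acid response genes had a median of -0.26, below all random lists, but of -0.08 at percentile 12.7 without the signal filter, with MTHFD2 (-0.86) and SLC7A11 (-0.68) at least 1.5-fold lower. The 13 heat shock genes had a median of -0.32 at percentile 0.11, but of -0.13 at percentile 8.8 against the mean Cy5 signal, and a bootstrap interval of -0.44 to 0.00 that just holds 0, with HSPD1 and BAG3 at -0.53, and no member reached 1.5-fold. The 22 cytoplasmic aminoacyl-tRNA synthetase genes had a median of -0.20 at percentile 0.46, with YARS1 (-0.59), EEF1E1 (-0.48) and CARS1 (-0.48) lowest and the lysine enzyme KARS1 at -0.23. The 70 ribosomal proteins stood at -0.09, percentile 0.40, and this list remained outside the bounds under 4 of 9 other settings, the synthetases under 5. Among the 21 p53 targets GDF15 (1.77), BTG2 (0.71) and CDKN1A (0.68) were at least 1.5-fold higher, with a list median of 0.16 at percentile 98.0.

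With 3'-Asp KD, given at the lower dose, fewer genes departed from 0. By the dye labels 23 genes were at least 2-fold higher and 27 lower, 12 and 39 when centred on all named genes, and the column names would make these 27 higher and 23 lower. These 0.23% and 0.26% of measured genes lie below the 0.68% of unchanged genes that passed in either direction in the simulation. Given the same limits of its error measure, the simulation does not show that these counts exceed those with no change. NEFL, a neurofilament subunit, was lowest at 3.19-fold, and the retinol dehydrogenase RDH10 (2.74-fold) and the histone gene H3C15 (3.45-fold) were among the highest. KLK3 was 1.96-fold lower with 2 probes that differed by an SD of 0.02. Its Cy5 signal had an SD of 0.56 between arrays, but its Cy3 signal moved in the same direction. Relative to the column's median, log2 Cy5 was 3.25, 3.69 and 2.58 on the 5'-Lys, 5'-Asp and 3'-Asp arrays. Log2 Cy3 was 2.54, 2.96 and 1.60.

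The other genes high in Cy3 on the 3'-Asp array were RNU2-1 (3.67-fold), TNFRSF12A (2.69-fold), a probe under the symbol HIST1H4C (2.64-fold), the transcription factor USF1 (2.49-fold), SNORA28 (2.45-fold), SNORA73A (2.30-fold), CCAR2 (2.29-fold), TMEM45A (2.24-fold) and SCARNA13 (2.23-fold). HIST1H4C is the former symbol of the histone gene H4C3, whose other probe had 1.12-fold. Low were KCND2 (2.74-fold), RFPL2 (2.61-fold) and its relative RFPL1 (2.40-fold), SAPCD1 (2.60-fold), SPOPL (2.59-fold), the potassium channel subunit KCNS3 (2.41-fold), EFCAB11 (2.40-fold), SEC14L1 (2.37-fold), the G protein subunit GNB4 (2.36-fold), the incretin receptor GIPR (2.32-fold) and IGFBP3 (2.28-fold), which binds insulin-like growth factors. RFPL1 and RFPL2 may share probe binding, EFCAB11 and SEC14L1 each had 2 probes that disagreed (SD of 1.24 and 1.12), and TMEM45A and SAPCD1 had Cy5 signals with an SD of 0.88 and 0.77.

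Of the lists, androgen-induced genes had a median of -0.28 with 3'-Asp KD, below all random lists. KLK2 (-1.01), KLK3 (-0.97), MAF (-0.79), KCNN2 (-0.77) and ACSL3 (-0.59) were at least 1.5-fold lower. The G1/S list was at -0.20, percentile 0.11, with MCM4 (-0.61) and CDC45 (-0.62) lower by that margin, while the G2/M list, at -0.14 and percentile 0.83, stayed inside the bounds although ANLN had -1.16. The ATF4 list had -0.23 at percentile 0.02 and the NRF2 list, of oxidative stress genes, -0.24 at percentile 0.16. The bootstrap interval of the NRF2 median, -0.41 to 0.10, holds 0, and 6 of its 15 members lay above 0. Both stood apart under 7 of 9 other settings. The ATF4 median was -0.15 without the signal filter (percentile 0.96) and with it at the 75th percentile (1.33), and the NRF2 median was -0.09 against the mean Cy5 signal (13.1) and with the filter at the 75th percentile (14.5). SLC7A11 (-1.07), the cystine transporter gene, belongs to both, and MTHFD2 (-0.72) and FTH1 (-0.59) were the other low members. All 14 histone genes had ratios above 0, with a median of 0.30 at percentile 99.99, and of 0.21 at percentile 99.3, inside the bounds, against the mean Cy5 signal.

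**Figure D2:**
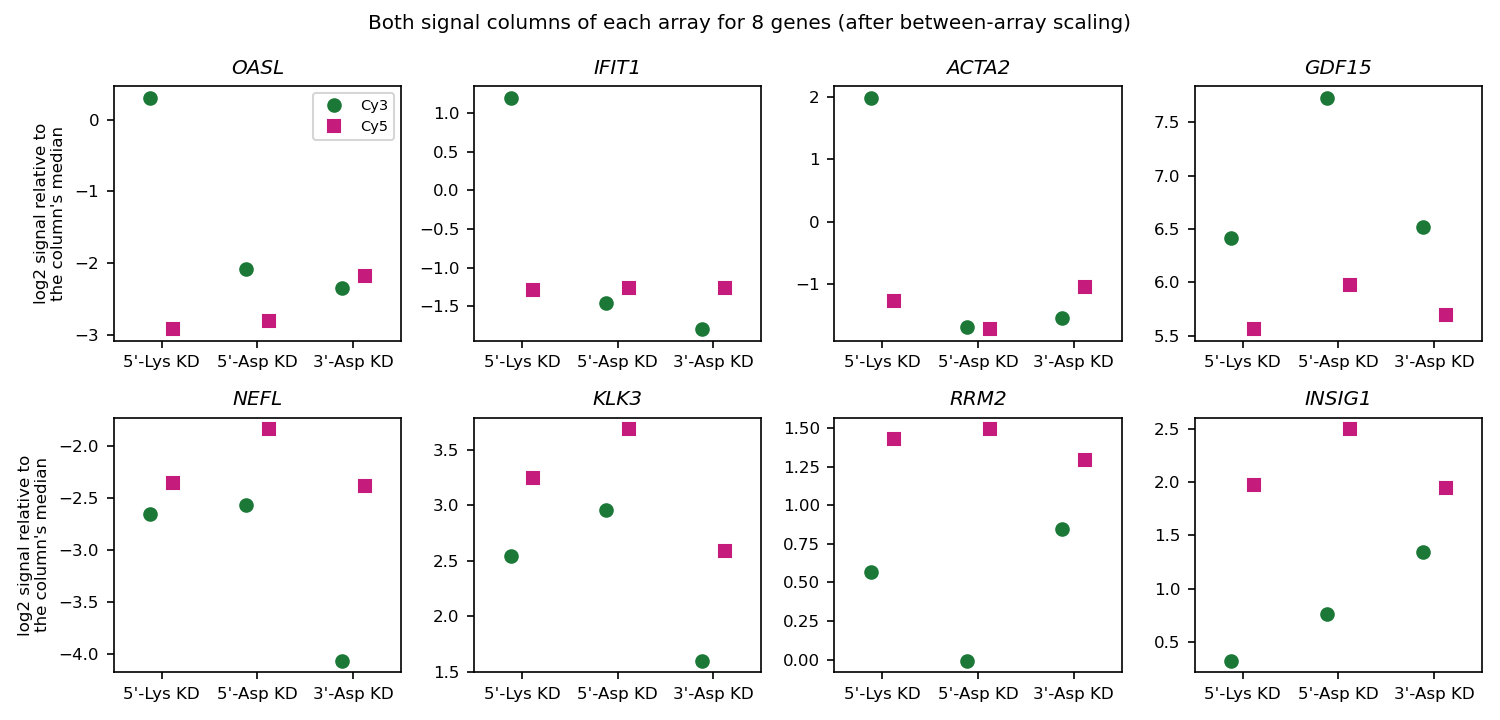
Log2 signal of 8 named genes in both signal columns of each array, relative to the column's median, after scaling between arrays. Circles are Cy3 and squares Cy5, and each panel has its own vertical range. OASL, IFIT1 and ACTA2 lie high in the Cy3 column of the 5'-Lys array alone, GDF15 is highest in the Cy3 column of the 5'-Asp array, and NEFL and KLK3 are lowest in the Cy3 column of the 3'-Asp array.

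The log2 ratios of the arrays went together across genes. Pearson r was 0.557 between 5'-Lys KD and 5'-Asp KD, 0.556 between the Asp knockdowns and 0.518 between 5'-Lys KD and 3'-Asp KD. By the column names the first and last would be -0.557 and -0.518. Genes are not independent replicates. Unchanged knockdowns set against 1 shared control gave r = 0.498 and a covariance of 0.0308 in simulation. The observed covariances were 0.0729, 0.0547 and 0.0601. The simulation gave knockdown and control the same SD, which sets r near its value whatever the data. It also took the SD of the Cy5 signal between arrays as the shared part. It therefore cannot show how much of the correlation a shared control gives. Whether 1 control RNA served all arrays is not given in the sources used here. The 9 metallothioneins had median log2 Cy5 signals, relative to the column's median, of 2.94, 4.25 and 3.21 on the 5'-Lys, 5'-Asp and 3'-Asp arrays. Their Cy3 medians were 2.20, 3.96 and 3.31. If Cy5 was the control throughout, a single control RNA would give equal Cy5 signals apart from array error. By the column names the control signals would be 2.94, 3.96 and 3.31, which differ too. But both dyes had the same order over the arrays, as arrays that themselves differ would give. These values therefore do not decide whether 1 control RNA served all arrays. Single controls cannot be split, so part of the correlation may come from a shared control or from a gene-specific dye effect.

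C1QTNF5, a secreted C1q-related protein gene, had the largest ratio on every array, 21.9-fold with 5'-Lys KD, 24.1-fold with 5'-Asp KD and 29.9-fold with 3'-Asp KD. At least 2-fold higher on all arrays were 9 genes, and 4 were lower. RNU2-1, the U2 spliceosomal RNA, had log2 ratios of 2.04, 1.83 and 1.87 in the same order. TNFRSF12A (1.43 or more), SNORA28 (1.30 or more), H3C15 (1.20 or more), SNORA73A (1.18 or more), SCARNA13 (1.16 or more), CIMIP2A (1.02 or more) and SERTAD3 (1.01 or more) completed the 9, and SNORA74A (0.97 or more) came next. The 4 low genes were RFXAP, the synaptotagmin gene SYT4, GIPR and ZNF385B, each at -1.08 or below, although the Cy5 signal of SYT4 had an SD of 1.41 between arrays. Lower on all arrays, but by less than 2-fold on at least 1 of them, were NIPA1, TM4SF1, the cell cycle repressor E2F8, GNB4, MIR17HG and FBXO4, all at -0.80 or below.

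Genes at least 2-fold higher with both 5'-Lys KD and 5'-Asp KD numbered 16, against 0.225 for independent lists, and 12 were lower with both, against 0.731. For the Asp knockdowns these were 10 (0.0834) and 7 (0.143), and for 5'-Lys KD and 3'-Asp KD 12 (0.140) and 6 (0.365). Unchanged knockdowns against 1 shared control gave 10.9 genes per direction in simulation, and the observed counts ran from 6 to 16. That simulation has the limits given above, so it does not show how many genes a shared control adds. By the column names the genes shared by 5'-Lys KD and either Asp knockdown would lie in opposite directions. At 1.5-fold 84 genes were higher on all arrays, 16 of them among the 27 measured small nuclear and nucleolar RNAs, and 32 were lower. Read by the column names, 0 and 1 genes would pass in all knockdowns.

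**Figure D3:**
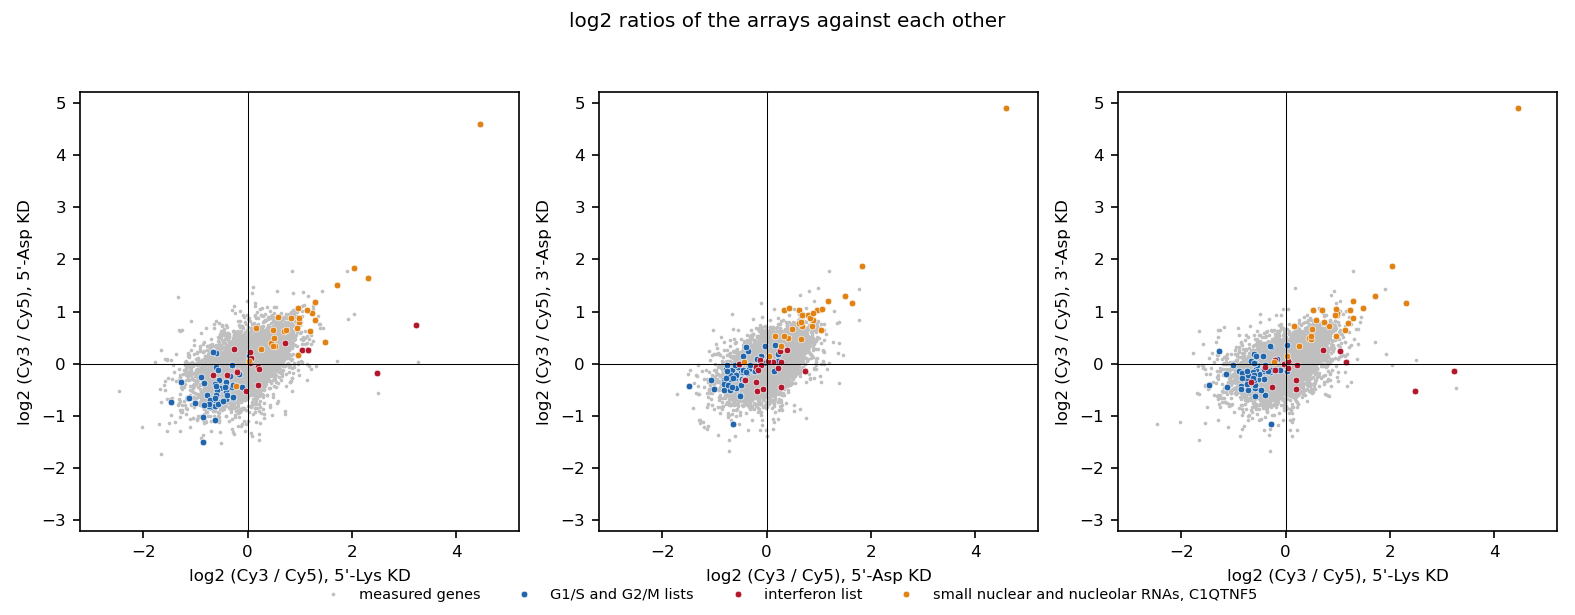
Log2 ratios (Cy3 over Cy5) of each pair of arrays, 1 point per measured gene. Cell cycle genes (blue) lie low on the axis of the 5'-Lys array, where their medians were -0.59, OASL and IFIT1 (red) lie far right on that axis, and the small RNAs with C1QTNF5 (orange) lie high on both axes.

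Read by the dye labels, differences between the arrays cancel any dye effect or shared control that is equal on both. By the column names, comparisons of 5'-Lys KD with either Asp knockdown become sums of the Cy3 over Cy5 ratios. In such sums a gene-specific dye effect adds up and does not cancel. Between 5'-Lys KD and 5'-Asp KD 164 genes differed at least 2-fold, 60 with the higher ratio in 5'-Lys KD and 104 with the lower. ACTA2, CEND1 and IFIT1 led the first set with differences of 3.22, 3.06 and 2.67, and after OASL, at 3.23 against 0.74, came TTR (1.67), SDHD (1.67), CLU (1.66), the activin antagonist FSTL3 (1.62), CYP4V2 (1.56) and MTCH2 (1.47). CAMK2N1, an inhibitor of a calmodulin-dependent kinase, led the second set with -2.62, followed by TMEFF2 (-1.96), SEMA3C (-1.95), RFX6 (-1.93), FYCO1 (-1.92), COL5A2 (-1.91) and GTF2E2 (-1.81). Of the lists outside the bounds, histones (0.40), interferon genes (0.27), p53 targets (0.26), oxidative phosphorylation (0.19) and tRNA processing genes (0.15) were relatively higher with 5'-Lys KD and androgen-induced genes (-0.18) relatively lower. The bootstrap interval of the interferon difference, -0.08 to 0.61, holds 0, and 10 members lay above 0 and 7 below. By the column names p53 targets (0.70), androgen-induced (-0.86), G1/S (-1.11), G2/M (-1.06) and ATF4 genes (-0.44) would lie outside the bounds. Histones (0.41), interferon genes (0.12), oxidative phosphorylation (0.08) and tRNA processing genes (-0.12) would lie inside.

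Between 5'-Lys KD and 3'-Asp KD, which also differ in dose, 151 genes differed at least 2-fold, 50 higher and 101 lower with 5'-Lys KD. ACTA2 (3.73), OASL (3.38), IFIT1 (3.01), CEND1 (2.42), BIRC3 (2.06), SYTL2 (1.73), DNAJB4 (1.60) and RELB (1.59) led the higher genes and RFX6 (-2.29), GTF2E2 (-1.98), SPRING1 (-1.96), ADD3 (-1.93), COL5A2 (-1.91), NCEH1 (-1.89) and PIMREG (-1.64) the lower. The G2/M list differed by -0.47, G1/S by -0.31 and unfolded protein response genes by -0.22, while p53 targets (0.30), NRF2 genes (0.23) and apoptosis regulators (0.21) lay relatively higher with 5'-Lys KD. By the column names histones (0.81), p53 targets (0.46), apoptosis regulators (0.42), androgen-induced (-0.79), G1/S (-0.88) and G2/M genes (-0.79) would lie outside the bounds, although the interval of the apoptosis regulators (-0.02 to 0.74) holds 0, and unfolded protein response (0.07) and NRF2 genes (-0.18) inside. With that reading 1091 and 894 genes would differ in these comparisons of 5'-Lys KD with 5'-Asp KD and 3'-Asp KD. A gene-specific dye effect does not cancel there, so these counts and the list values by the column names can hold it.

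The Asp knockdowns, which also differ in dose, differed least. Here 72 genes were at least 2-fold apart, 37 higher and 35 lower with 5'-Asp KD, a count that the column names leave at 72. ADRA2A (1.79), NBEA (1.76), RFPL2 (1.39), the NF-kB subunit RELB (1.39) and C1QTNF6 (1.31) had the higher ratio with 5'-Asp KD. The lower side held ADD3 (-1.66), GPRIN2 (-1.61), PUDP (-1.38), PDE12 (-1.36), SDHD (-1.35), TTR (-1.34), TXNDC15 (-1.31) and KIFBP (-1.31). Both cell cycle lists differed by -0.33, histones by -0.24, unfolded protein response genes by -0.18 (bootstrap interval -0.30 to 0.03, which holds 0) and oxidative phosphorylation genes by -0.17. Androgen-induced genes stayed inside the bounds, at 0.13 (-0.02 to 0.24). They also did so between 5'-Lys KD and 3'-Asp KD, at -0.15 (-0.38 to 0.06). A dye effect or shared control therefore stays open for their low ratios too. For ADRA2A the Cy5 signal had an SD of 1.05 between arrays.

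Other lists close to tRNA and small RNA biology stayed inside the bounds on each array. The 37 genes of tRNA transcription, processing and cleavage had medians of 0.09, -0.10 and 0.01 for 5'-Lys KD, 5'-Asp KD and 3'-Asp KD, and ANG, the gene of angiogenin, had 0.32, -0.48 and 0.01. The 17 small RNA silencing genes had medians of -0.03, 0.11 and 0.06, within which DICER1, the nuclease that makes microRNAs, had 0.63, 0.76 and 1.07 and TSN, a subunit of the passenger strand nuclease, -0.03, -1.15 and -0.11. The 32 translation factors had 0.01, 0.05 and 0.03, with EIF5A at 0.70, 0.55 and 0.77. Ribosome biogenesis and MYC target genes had 0.00, -0.11 and -0.06, with MYC itself at 0.25, 0.70 and -0.06, although its 2 probes disagreed with an SD of 0.80 on the first and 0.65 on the second of these arrays.

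The remaining lists also stayed inside the bounds, with medians given in the same order. The 19 cholesterol synthesis genes had 0.13, -0.02 and 0.04 despite INSIG1, and the 14 fatty acid synthesis genes -0.06, -0.14 and -0.12, with ACSL3 at -0.95, -0.64 and -0.59. The 20 glycolysis and hypoxia genes had 0.04, -0.07 and 0.00, the 30 oxidative phosphorylation genes 0.16, -0.05 and 0.08, and the 17 unfolded protein response genes -0.08, 0.00 and 0.13. The 10 hormone receptor cofactors had -0.09, 0.08 and -0.03, with HOXB13 at -0.74 on the 5'-Lys array. The 13 luminal epithelial genes had -0.02, -0.01 and 0.10, with KRT19 at -0.56, -0.63 and -0.79, and the 9 metallothioneins -0.01, 0.05 and 0.12. The 5 measured matrix genes had 0.47, 0.03 and 0.18, with CCN1 at 0.96 and VIM at -0.48 on the 5'-Lys array. Markers of basal (4 measured), neuroendocrine (3), stromal (2) and immune cells (1) were too few for a percentile, and of these TUBB3 and ACTA2 are described above and CD79A had 0.58, 0.48 and 0.21.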

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

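The reading by the column names was chosen after the values were seen. Read by the dye labels, 2 measured genes had ratios in opposite directions between knockdowns, of at least 2-fold on both arrays or, among genes named for a knockdown, of at least 1.5-fold on both. CAMK2N1, an inhibitor of a calmodulin-dependent kinase, was 2.52-fold lower with 5'-Lys KD and 2.43-fold higher with 5'-Asp KD, a log2 difference of -2.62. RFX6 was 3.16-fold lower with 5'-Lys KD and 1.55-fold higher with 3'-Asp KD, a log2 difference of -2.29. Among all measured genes at 1.5-fold on both arrays, 2 were higher with 5'-Lys KD and lower with 5'-Asp KD and 10 the reverse. For 5'-Asp KD and 3'-Asp KD these were 2 and 3, and for 5'-Lys KD and 3'-Asp KD 2 and 6. With 1 array per knockdown neither difference was tested. By the column names both genes would be lower in both knockdowns. No group had enough arrays to look for outlying samples.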

How the results depend on the processing

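The alternatives that use the column names, centre on all named genes or leave out small RNAs and C1QTNF5 were chosen after the data were seen, the others before. With 1 array per knockdown no array could be left out, and no paired analysis was possible because there are no replicates. Gene list medians outside the random bounds numbered 19 in the main setting and 13 to 19 under the 9 others tried for lists, which leave out the column names. Under these 9 all 19 kept their sign, except that of histones with 5'-Lys KD, which was -0.076 against the mean Cy5 signal of all arrays. Androgen-induced and G1/S genes on each array, and G2/M genes on the 5'-Lys and 5'-Asp arrays, stood apart under all 9. The column names would turn the sign of the 7 medians on the 5'-Asp array and the 5 on the 3'-Asp array. Of single list medians 283 values stayed close, 13 moved and 1 reversed, and of named genes 284 stayed close and 76 moved. The cause of these shifts was not tested, except where the construction of a setting gives it. Low signal limits these values, and no detection flags were used.

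With the column names in place of the dye labels, the correlation across genes became -0.557 for 5'-Lys KD and 5'-Asp KD and -0.518 for 5'-Lys KD and 3'-Asp KD, since 1 array of each pair changes sign. The genes differing at least 2-fold became 1091 and 894 for these pairs, counts in which a gene-specific dye effect does not cancel. The median SD of the control signal became 0.17.

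Without a filter on signal, which adds dim genes, genes at least 2-fold higher and lower numbered 553 and 612 for 5'-Lys KD, 516 and 467 for 5'-Asp KD, and 554 and 412 for 3'-Asp KD. Differing genes numbered 1455 between 5'-Lys KD and 5'-Asp KD, 1223 between the Asp knockdowns and 1442 between 5'-Lys KD and 3'-Asp KD, and the first of these pairs had r = 0.505. With the filter at the 75th percentile, which leaves fewer genes, higher and lower genes were 22 and 61, 13 and 24, and 7 and 7 for the knockdowns in the same order. Differing genes were then 63, 23 and 43, with r of 0.579, 0.594 and 0.594 for the pairs in that order.

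At a 1.5-fold threshold, which is wider by construction, 458 genes were higher and 709 lower with 5'-Lys KD, 361 and 444 with 5'-Asp KD, and 235 and 261 with 3'-Asp KD, and 842, 576 and 851 genes differed for the pairs in the order above. After normexp correction with an offset of 50, 26 genes were at least 2-fold lower with 5'-Asp KD, 14 were higher with 3'-Asp KD, and 105, 40 and 92 differed for the pairs in that order. The offset draws ratios of dim probes towards 0. Against the mean Cy5 signal of all arrays r was 0.452 for 5'-Lys KD and 5'-Asp KD, 0.634 for the Asp knockdowns and 0.477 for 5'-Lys KD and 3'-Asp KD. Genes at least 2-fold higher with 3'-Asp KD numbered 12 when centred on all named genes and 13 without small RNAs and C1QTNF5.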

Other observations

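All tests in this part were chosen after the results were seen. Setting each signal column against the other 5 gives values that do not depend on which column is called the knockdown. Outside all others by at least 1.5-fold were 213 genes in the Cy3 column of the 5'-Lys array, 62 in that of the 5'-Asp array and 42 in that of the 3'-Asp array. The Cy5 columns held 11, 38 and 1. Below all other columns in the Cy3 column of the 5'-Lys array were GTF2E2 (by 1.78 on the log2 scale), PIMREG (1.56), SPRING1 (1.52), TMTC2 (1.52) and the ceramide synthase CERS6 (1.43). In the Cy3 column of the 5'-Asp array GDF15 stood above all others by 1.22 and KIFBP (1.29), CYP4V2 (1.13) and SDHD (1.04) below. In that of the 3'-Asp array INHBB, an activin subunit gene, stood above by 1.03 and NEFL (1.41) and RFPL2 (1.34) below. The Cy5 column of the 5'-Lys array held SYT4 2.03 above all others.

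The lower cell cycle genes in Cy3 were examined for a dye effect or shared control, which would give the same list median on every array. Between 5'-Lys KD and 3'-Asp KD the median of the G1/S genes differed by -0.31 (bootstrap interval -0.42 to -0.22) and that of the G2/M genes by -0.47 (-0.59 to -0.35). These intervals draw genes of single arrays and hold no spread between arrays or cultures. The pair was also chosen after its medians were seen, so the differences do not decide whether either is the whole cause. Between 5'-Lys KD and 5'-Asp KD the differences were 0.04 (-0.08 to 0.13) and -0.06 (-0.16 to 0.02), and both intervals hold 0. If the column names were right, the Cy5 columns of the Asp arrays should hold more genes outside all others than the Cy3 columns, but the counts were 38 against 62 and 1 against 42, which a control culture that itself differed could also give, so the 2 directions cannot be told apart. Across the G1/S genes Pearson r was 0.25 between 5'-Lys KD and 5'-Asp KD, 0.57 between the Asp knockdowns and -0.16 between 5'-Lys KD and 3'-Asp KD. For the G2/M genes it was 0.60, 0.63 and 0.37. A ratio set by the dye alone should repeat gene by gene, but error of single genes lowers r, and r does not register a shift common to a list. A response of the knocked-down cells and a dye effect or shared control, in part or as the whole cause, stay open.

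Small nuclear and nucleolar RNAs and C1QTNF5, chosen after they were seen high on every array, repeated their ratios with Pearson r of 0.91 or more across 28 genes for each pair, and of 0.81 or more across 27 without C1QTNF5. Cytoplasmic ribosomal proteins had r from 0.75 to 0.88 over medians near 0. A gene-specific dye effect may repeat a ratio in this way, and so may a shared control or a response common to all knockdowns. By the dye labels these explanations cannot be told apart, because all arrays then have 1 dye orientation. By the column names the knockdown was in Cy5 on both Asp arrays. A shared control or common response would then turn its sign between these and the 5'-Lys array, which the ratios did not, whereas a dye effect would not. Since the direction is not settled, these explanations stay open.

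The high OASL, IFIT1 and ACTA2 with 5'-Lys KD may be a response to this siRNA or to loss of its target, 2 biological explanations that the design does not separate. Each of these genes had 1 probe, so faults of single spots were tested on the interferon genes other than OASL and IFIT1. At least 1.5-fold higher were 3 of these 15, at percentile 97.8 of matched random lists, whose median was 1 gene, which leaves such faults open. Stromal cells as the source of ACTA2 (3.26) stay open too, since 5 of the 6 collagen and proteoglycan genes compared, with a median log2 ratio of 0.58, lay below the signal limit for measured genes, while COL1A1, the measured one, had 0.47 and LUM the highest value, 0.94. The other stromal genes were all below that limit by their mean signal over all columns. Of these, MYL9, a myosin light chain of contractile cells, had 2.93. Its log2 signals on this array were 8.85 in Cy3 and 5.91 in Cy5, so it was not near the floor here. TAGLN, also of contractile cells, had 0.38, THY1 0.68, PDGFRB 0.62 and FBLN1 -0.34. The negative control probe of this array had an intensity of 4.59 in Cy3 and 2.81 in Cy5, so ratios near the floor can lie above 0 without a change. COL1A2, COL3A1, COL6A3, DCN and THY1 had log2 Cy3 signals of 2.07 to 2.47, near that floor, so their ratios do not show raised stromal genes.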
